A study of Mus musculus with 30 samples.

How the data were processed

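Each library came from the left liver lobe of a mouse, per the labels' protocols, with poly(A) selection and a directional library kit. Per the submitters' processing notes, the tools were HISAT2 2.1.0 (a spliced aligner), SAMtools 1.9 and StringTie 2.0.3 (a transcript assembler and quantifier), and the build was GRCm38, also called mm10. The annotation used and the strand setting of the quantification are not given in the sources used here. The deposited values were FPKM per gene, normalized by the authors to transcript length and to the mapped fragments of each library, so no test for counts was run. The file held 29117 genes in 30 libraries, all of whose columns carried a sample's title. No cell held exactly 0, and 32.2% of the cells held no value. Cells without a value were set to 0 FPKM, which concerned 893 of the genes tested in at least 1 library. Where a gene shares reads with a near-identical copy or overlaps another gene, as with the Mup, Saa, Mt and hemoglobin families, the split of reads between copies was made by the authors' quantification and the values are uncertain.

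Groups were taken from the sample titles, which give the treatment and 2 numbers. The number with 3 levels was read as the replicate and the number with 5 levels as the sampling point, because the series design states 5 time points in triplicate. Lanes were taken from the sample descriptions, which name 5 lanes. Lanes 1 and 2 held 6 and 9 insulin libraries, and lanes 3, 4 and 5 held 5 PBS libraries each. Each PBS replicate number therefore has its own lane number. On lane 2 the same index, the barcode of a library, recurs among insulin libraries. Equal lane numbers may therefore stand for more than 1 sequencing run. The labels treat each library as a separate sample, and where samples are not from separate animals the p-values measure only the spread between samples.

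Depth was estimated per library from genes with a single annotated transcript longer than 300 bases, whose low values fall on steps of 1 read. At the best-fitting depth 34.4% to 41.2% of these values were whole numbers of reads within 0.05, so the estimate is rough and no reads were recovered. The estimates ranged from 20.0 to 40.7 M reads. No pair of libraries in a group shared values (identical values in at most 0.0103% of genes), and none was treated as a repeat.

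Genes at FPKM 1 or more in at least 3 of the 30 libraries were tested, which left 13589. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 10 groups, an intensity trend and 20 residual degrees of freedom, so that all groups shared an estimate of the spread. Insulin was compared with PBS at each point, F tests asked whether that difference depended on the point and whether each treatment varied among points, and p-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Before the data were examined, 31 gene lists were fixed (liver programmes, responses, zones, other cell types and RNA quality) and tested with camera in limma at a preset correlation of 0.01 for lists of at least 3 measured genes. Camera compares the genes of a list with all other genes tested. Some lists share members, so their calls are not separate evidence. Adjusted p-values were taken over all 130 tests of a list at a point. Camera called 22 of the 130, 17 higher and 5 lower, and 4 held with an estimated correlation: immediate early genes and CREB targets at point 2, CREB targets at point 3 and glucocorticoid receptor targets at point 1.

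The named genes were set by a rule fixed before the data were examined. It took 6 textbook insulin targets at every point, the 8 highest and 8 lowest genes per comparison that passed the test, whose 3 insulin libraries all lay above or below the 3 PBS libraries, at a mean of 1 FPKM or more and with a proper gene symbol, and up to 4 genes per list with the smallest adjusted p. For the F tests it took the 8 genes with the widest range. Members of a list given only to say which ones rose or fell, and CT010467.1, were named outside the rule after their values were seen. Some genes that the rule names are not reported here. Gene positions were taken from GENCODE M21 on GRCm38, matched by gene ID, which found 29066 of the 29117 IDs.

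The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, the replicate number as a block, lane or series as a random or fixed effect, a fit of only the 6 libraries of a point, each library or series left out in turn, and, for the lists, an estimated correlation and fry. The scripts were tested on simulated log2 values with the real spread and 200 changed genes among 13589. The changed genes were drawn from those at a mean of 5 FPKM or more, and the change was added on the transformed scale. Recovery among lower genes was therefore not measured. The noise was drawn independently for each gene and library, without likeness among the libraries of a series and without shifts of whole libraries. The numbers of false calls therefore do not carry over to the real data. For insulin minus PBS at point 2, 85.1% of 67 genes changed 2-fold and 41.8% of 67 changed 1.5-fold were recovered, with 5 false calls. For the interaction with genes changed at point 2, 67.2% and 8.96% were recovered, with 6 false calls. Other points differed. Recovery of 2-fold changes in insulin minus PBS ran from 76.1% at point 5 to 92.5% at point 1, with up to 14 false calls, at point 4. For the interaction it ran from 52.2% at points 4 and 5 to 73.1% at point 1. For genes changed at point 4 within PBS and within insulin, 82.1% and 89.6% of those changed 2-fold were recovered. Other calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.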

Results

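Liver transcripts were measured by poly(A) RNA sequencing in 10-week-old C57BL/6J mice, an inbred laboratory strain, that had been fasted for 12 to 16 h and then injected with human insulin at 0.7 U/kg or with phosphate-buffered saline (PBS), the vehicle control. The series holds 30 libraries of the left liver lobe, 15 per treatment, at 5 sampling points over 4 h with 3 libraries per treatment and point. The labels number the points from 1 to 5 without giving minutes, so the points are named by number here, and neither their order in time nor an uninjected baseline at point 1 is assumed. The deposited values were FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for 29117 genes. The depth, estimated from the steps between low values, ranged from 20.0 to 40.7 M reads per library, with medians of 30.7 M for insulin and 32.1 M for PBS. The question of each comparison was which liver transcripts differed between insulin and PBS at a given point. No sequencing lane held libraries of both treatments, so lane and treatment cannot be told apart in any single-point comparison. Libraries of a group correlated at Pearson r of 0.982 to 0.991 across genes on the log2(FPKM + 1) scale. Below, a gene rose or fell when its insulin libraries differed from the PBS libraries of the same point in limma's test at an adjusted p below 0.05. A list called higher or lower by camera, a test of gene lists, stood so relative to the other genes tested and not necessarily against PBS. Every size given is a difference of log2(FPKM + 1), which understates the change of low genes.

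The number of genes that differed was 1 at point 1, 184 at point 2, 1284 at point 3, 1799 at point 4 and 2596 at point 5, of 13589 tested. Of these, 84 rose and 100 fell at point 2, and 298 rose and 986 fell at point 3. A further 383 rose and 1416 fell at point 4. At point 5, 402 rose and 2194 fell. The balance of directions depended on the scaling of the libraries, because the median difference of all genes was -0.06, -0.12, -0.14, -0.14 and -0.17 on the log2 scale at points 1 to 5. With median-ratio scaling, which moved each of these medians to within 0.02 of 0, 149 genes rose and 57 fell at point 2, 693 and 485 at point 3, 943 and 801 at point 4, and 1196 and 1085 at point 5. With quantile normalization the numbers were 138 and 60, 665 and 507, 975 and 788, and 1121 and 1077. Genes with a difference of 2-fold or more were fewer, with 60 higher and 22 lower at point 2, 69 and 90 at point 3, 58 and 155 at point 4, and 56 and 201 at point 5. The 3 insulin libraries lay apart from the 3 PBS libraries for 9.43%, 23.5%, 35.5%, 32.4% and 35.4% of the genes at points 1 to 5, where chance gives 10%. None of the named genes that passed the test changed direction under either scaling.

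**Figure D1:**
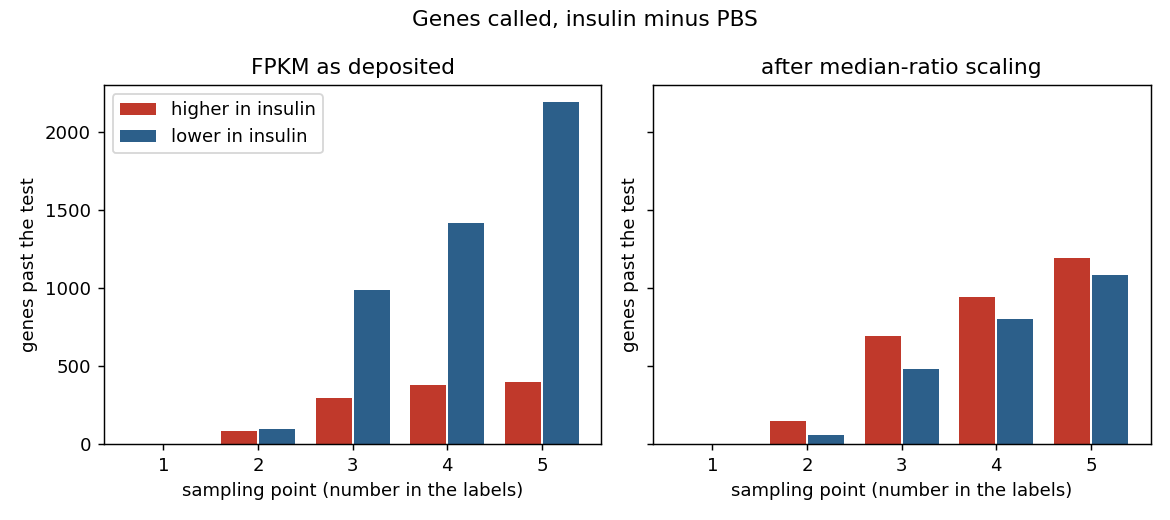
Genes past limma's test at each sampling point, as bars counting genes higher (red) and lower (blue) in insulin than in PBS, with 3 libraries per treatment and point; the left panel uses FPKM as deposited and the right panel FPKM after median-ratio scaling. At point 5 the bars stand at 402 higher and 2194 lower on the left, and at 1196 higher and 1085 lower on the right.

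Among the genes chosen beforehand as textbook targets of insulin in liver, Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, passed the test at none of the 5 points. Its differences were -0.31, 0.02, 0.01, -0.05 and 0.04, with a standard error of 0.16 each, at group means of 1169 to 1460 FPKM. G6pc, the catalytic subunit of glucose-6-phosphatase, was higher in insulin at point 2 by 1.19 ± 0.30 (SE, n = 3 per group, adjusted p = 0.0406), at point 4 by 1.36 ± 0.30 (adjusted p = 0.00521) and at point 5 by 0.97 ± 0.30 (adjusted p = 0.0244). The point 2 call of G6pc ended under 9 of 19 alternatives, among them without insulin replicate 2 or 3 (adjusted p = 0.181 and 0.109) or without PBS replicate 1, 2 or 3 (adjusted p = 0.0638, 0.153 and 0.109). Its point 5 call ended under 7 of 19, among them without insulin replicate 1 or 3 (adjusted p = 0.0514 and 0.0928) or without PBS replicate 2 or 3 (adjusted p = 0.0509 and 0.132). Igfbp1, a secreted binding protein of insulin-like growth factors, reached 396 ± 150 FPKM (SD, n = 3) in insulin against 37.0 ± 13.9 in PBS at point 4, a difference of 3.36 ± 0.55 (SE, adjusted p = 0.000481). At point 5 the Igfbp1 difference was 2.36 ± 0.55 (adjusted p = 0.00525). Irs2, an adaptor of the insulin receptor, stood at 16.8 ± 4.42 FPKM in insulin and 2.03 ± 0.644 in PBS at point 2, a difference of 2.54 ± 0.38 (SE, adjusted p = 0.000299), and passed at no other point. Srebf1, which encodes the lipogenic transcription factor SREBP-1, fell at point 5, to 1.93 ± 0.474 FPKM against 7.52 ± 0.542 in PBS, a difference of -1.55 ± 0.24 (adjusted p = 0.000198). No direction was set beforehand for these textbook targets. A pass therefore does not show that a gene moved as the known action of insulin would move it.

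**Figure D2:**
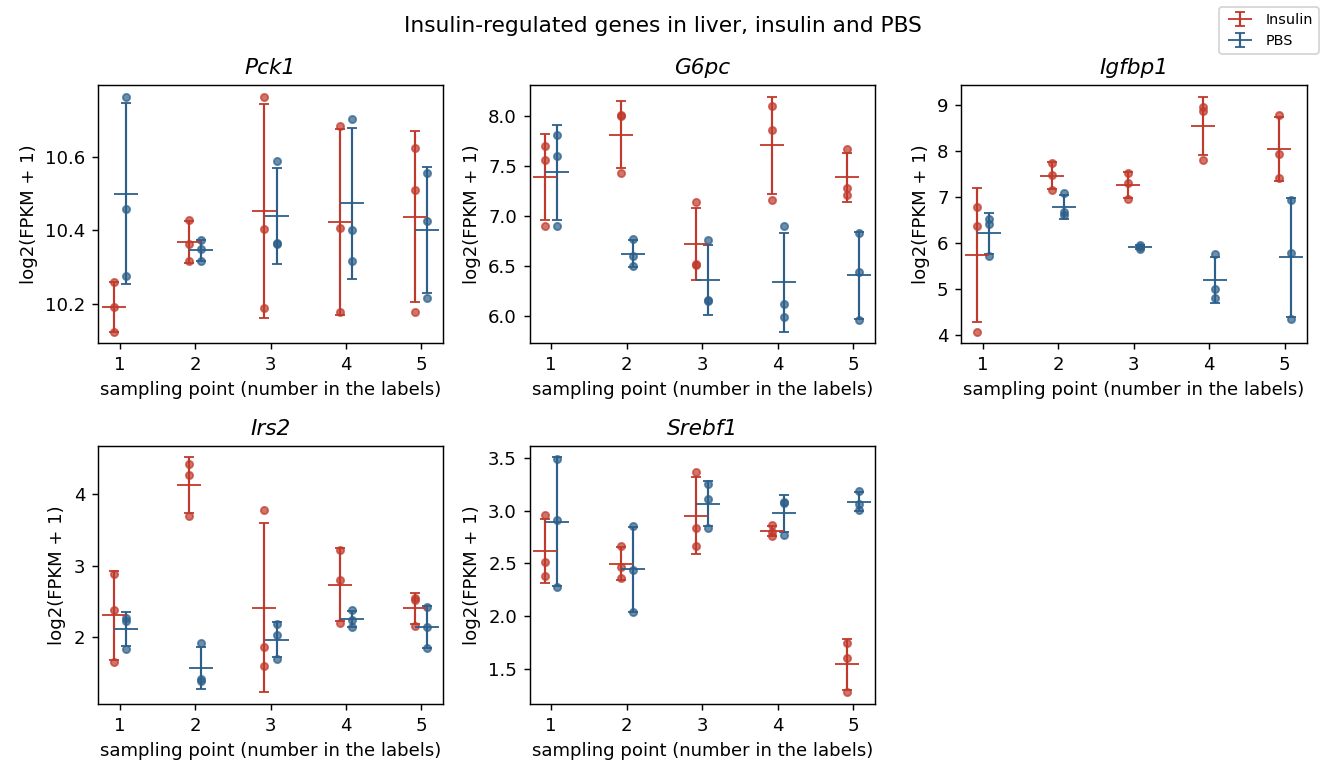
Log2(FPKM + 1) of Pck1, G6pc, Igfbp1, Irs2 and Srebf1 at each numbered sampling point, for insulin (red) and PBS (blue), with a point per library, a dash at the mean of the 3 libraries and bars of 1 SD. Igfbp1 at point 4 stands at a mean of 396 FPKM in insulin and 37.0 FPKM in PBS, whereas Pck1 lies between means of 1169 and 1460 FPKM in every group; each panel has its own vertical range, which does not start at 0.

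At point 1, a single gene passed the test. Lpin1 (chromosome 12, 16535669 to 16610966 in GRCm38), which encodes the phosphatidate phosphatase lipin 1, was lower in insulin, at 5.88 ± 2.04 FPKM against 24.6 ± 12.1 in PBS (SD, n = 3), a difference of -1.83 ± 0.28 (SE, adjusted p = 0.0107). The 15 measured glucocorticoid receptor targets shifted lower as a list, with a median of -0.70. Of them, 9 fell when adjusted over the list alone, against 1, Lpin1, over all genes tested. The list was called by camera (adjusted p = 7.06e-12) and the call held with an estimated correlation (adjusted p = 0.0131). The metal-binding metallothioneins Mt1 and Mt2 differed by -1.96 ± 0.39 and -1.95 ± 0.41 without passing over all genes (adjusted p = 0.118 and 0.16). Camera also called the gluconeogenesis list lower at point 1 (adjusted p = 0.000569), a call that ended at adjusted p = 0.664 with an estimated correlation. Of its 13 members 0 passed over all genes, and 1 was lower when adjusted over the list alone. At an unadjusted p under 0.05, 1078 genes differed in limma's test. The call of Lpin1 ended without insulin replicate 2 (adjusted p = 0.0835) or insulin replicate 3 (adjusted p = 0.0907), and with only the 6 libraries of the point in the fit (adjusted p = 0.854). The genes called at point 1 numbered 3 without insulin replicate 1, 0 without insulin replicate 2 or 3, 62 without PBS replicate 1 and 2 without PBS replicate 2 or 3.

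At point 2, immediate early genes and targets of the cAMP-responsive factor CREB were higher in insulin than in PBS. Nr4a1 (chromosome 15, 101254269 to 101274795), an orphan nuclear receptor induced early by many stimuli, stood at 57.7 ± 9.12 FPKM against 1.06 ± 0.411 (SD, n = 3), a difference of 4.84 ± 0.38 (SE, adjusted p = 1.82e-08). Of the 18 immediate early genes measured, 10 rose and 2 fell, and 12 rose and 2 fell when adjusted over the list alone. Atf3 rose by 3.11 ± 0.38, Btg2 by 2.42 ± 0.44 and the phosphatase gene Dusp1 by 2.30 ± 0.26, while Egr1 and Klf10 fell by 1.84 and 1.94. The call of Egr1 ended under 8 of 19 alternatives, among them without insulin replicate 1, 2 or 3 (adjusted p = 0.106, 0.126 and 0.0703) or without PBS replicate 2 or 3 (adjusted p = 0.145 and 0.208). Of the 13 CREB targets, 8 rose and 0 fell (9 and 0 over the list alone), among them the salt-inducible kinase Sik1 by 3.55 ± 0.41, Nr4a3 by 2.18 ± 0.31 and Crem by 1.16. Camera called both lists (adjusted p = 2.63e-20 and 4.17e-18), and both calls held with an estimated correlation (adjusted p = 0.0131 for each).

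Other genes higher in insulin at point 2 were the mitochondrial carrier Slc25a25 at 2.57 ± 0.44, Irs2, and the ligand Efna1 at 2.31 ± 0.33. The lowest was Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G protein signalling, at 1.78 ± 0.911 FPKM against 55.9 ± 18.4, a difference of -4.35 ± 0.48 (SE, adjusted p = 6.93e-06). Depp1 fell by 2.31, Osgin1 by 2.26, Txnip, a thioredoxin-binding arrestin, by 1.85, and Angptl4, an inhibitor of lipoprotein lipase, by 1.89. Of 23 genes of fatty acid oxidation and ketogenesis, 3 fell (Angptl4, the lipid droplet protein Plin2 by 0.94 and the ketone enzyme Bdh1 by 0.61) and 0 rose. The call of Plin2 ended without insulin replicate 1 or 2 (adjusted p = 0.0974 and 0.171) or PBS replicate 2 or 3 (adjusted p = 0.117 and 0.165), and that of Bdh1 without PBS replicate 2 (adjusted p = 0.0675). The number that fell was 5 without PBS replicate 1 and 1 without PBS replicate 2. Adjusted over the list alone, 16 fell, and with quantile normalization 2 fell. Camera called this list lower (adjusted p = 1.02e-09), which ended at adjusted p = 0.531 with an estimated correlation. The list median of -0.46 was -0.31 with median-ratio scaling. Clock genes were called higher (adjusted p = 0.000183, and adjusted p = 0.409 with an estimated correlation), with 2 of 17 risen, Nfil3 by 1.97 ± 0.27 and Per1 by 0.75 ± 0.16, and 5 risen with 1 fallen over the list alone. Under either scaling 4 clock genes rose. The call of Per1 ended without insulin replicate 2 (adjusted p = 0.0856) or PBS replicate 2 (adjusted p = 0.0599). At point 2, 62 genes were called with only its 6 libraries in the fit. It was 120 without insulin replicate 1, 84 without insulin replicate 2, 456 without PBS replicate 1, and 85 without PBS replicate 2 or PBS replicate 3. The CREB targets that rose numbered 3 without insulin replicate 2, 4 without PBS replicate 2 and 5 without PBS replicate 3.

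At point 3, the highest differences included CREB targets. Ppargc1a (chromosome 5, 51454250 to 51567726), which encodes the transcriptional coactivator PGC-1alpha, stood at 17.0 ± 3.57 FPKM in insulin against 1.85 ± 0.218 in PBS (SD, n = 3), a difference of 2.64 ± 0.14 (SE, adjusted p = 1.76e-11). Of the 13 CREB targets 6 rose and 0 fell (7 and 0 over the list alone), including Nr4a1 by 2.71 ± 0.38, Nr4a3 by 2.53 ± 0.31 and Crem by 2.12 ± 0.30. Camera called the list (adjusted p = 2.35e-14) and the call held with an estimated correlation (adjusted p = 0.0282). Pmvk, the phosphomevalonate kinase of sterol synthesis, rose by 2.41 ± 0.46. So did Trp53inp1 by 2.00 ± 0.19, the calcineurin regulator Rcan1 by 1.99 ± 0.16, Jaml by 2.19 ± 0.31 and Got1, the cytosolic aspartate aminotransferase, by 1.42 ± 0.25. Rgs16 fell by 2.99, the chromatin remodeller Chd9 by 1.88, the forkhead factor Foxq1 by 1.86, Osgin1 by 1.75, the receptor Erbb3 by 1.71 and the chemokine Cxcl1 by 1.68.

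Among the fixed lists at point 3, 5 of 23 genes of fatty acid oxidation fell and 0 rose (6 and 0 over the list alone), including the nuclear receptor Ppara by 0.91 and Bdh1 by 0.59, and 3 fell without insulin replicate 2 or PBS replicate 3. Camera called that list lower (adjusted p = 0.0242, adjusted p = 0.154 without insulin series 2, 0.0778 without PBS replicate 3 of point 3, adjusted p = 0.1 with median-ratio scaling, and adjusted p = 0.975 with an estimated correlation). Of 18 immediate early genes 3 rose and 1, Junb, fell, and camera called them higher (adjusted p = 0.00382, and adjusted p = 0.975 with an estimated correlation). That list call ended without insulin series 2 (adjusted p = 0.0569) or with median-ratio scaling (adjusted p = 0.0726). The call of Junb ended without insulin replicate 1 or 3 (adjusted p = 0.13 and 0.0553) or PBS replicate 1, 2 or 3 (adjusted p = 0.0507, 0.0865 and 0.0967). Of 17 clock genes 3 rose (Cry1 by 0.98, Nfil3 by 1.41 and Per2). In the same list 4 fell, including Dbp by 1.57, with 3 and 6 over the list alone and 3 and 3 under either scaling. The number that fell was 2, 1, 1 and 2 without insulin replicate 1, insulin replicate 2, PBS replicate 2 and PBS replicate 3. Of 12 autophagy and lysosome genes 4 fell and 0 rose as deposited, counts that were 2 and 0 with median-ratio scaling and 2 and 1 with quantile normalization. Without insulin replicate 3 or PBS replicate 1 a single autophagy gene fell, and 2 fell without any of the other 4 libraries. Camera called neither the clock nor the autophagy list at point 3, where 986 of all 13589 genes fell. Camera called ribosome biogenesis higher (adjusted p = 0.0407, and adjusted p = 0.975 with an estimated correlation) with 1 of 21 members risen, Gnl3 by 0.58. The median difference of that list was 0.04 as deposited. Risen members numbered 4 with median-ratio scaling and 3 with quantile normalization. Mitochondrially encoded mRNA was also called higher (adjusted p = 0.000351, and adjusted p = 0.975 with an estimated correlation) with 0 of 13 members passing, or 1 higher with median-ratio scaling. The ribosome biogenesis call ended without insulin series 3 (adjusted p = 0.0621) or PBS series 1 or 2 (adjusted p = 0.0604 and 0.0524). That of Gnl3 ended without insulin replicate 2 or 3 (adjusted p = 0.0696 and 0.104) or PBS replicate 1 or 2 (adjusted p = 0.0865 and 0.0585). The count of genes called at point 3 moved with each library left out, to 724, 590 and 845 without insulin replicates 1, 2 and 3 and to 632, 602 and 583 without PBS replicates 1, 2 and 3. Without the filter on low values it was 810, and without the insulin replicate 1 series, which holds more ribosomal RNA, it was 693.

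At point 4, Igfbp1, Pdk4, Ddit4 and Txnip were among the genes higher in insulin. Pdk4 (chromosome 6, 5483351 to 5496309), a kinase that inhibits pyruvate dehydrogenase, stood at 33.3 ± 9.15 FPKM against 2.42 ± 0.429 in PBS (SD, n = 3), a difference of 3.30 ± 0.26 (SE, adjusted p = 3.58e-08). Ddit4, Gadd45g, Trp53inp1, Plk3 and Cdkn1a rose by 2.29 ± 0.37, 2.23 ± 0.33, 2.15 ± 0.19, 1.87 ± 0.38 and 1.79 ± 0.43, and Txnip by 1.71 ± 0.16. The call of Cdkn1a ended without insulin replicate 2 (adjusted p = 0.0628). Of 18 genes of the insulin receptor and Foxo target list, 5 rose (Igfbp1, Pdk4, Txnip, Foxo1 by 0.52 and Ccng2 by 0.91) and 1, the activin subunit gene Inhbe, fell by 2.03. The counts over the list alone were also 5 and 1, and under either scaling 7 and 1. Camera called the list higher (adjusted p = 1.53e-05, and adjusted p = 0.144 with an estimated correlation). Of 15 glucocorticoid receptor targets 4 rose and 0 fell as deposited (5 and 0 over the list alone), including the tyrosine aminotransferase gene Tat by 1.26 ± 0.22, and 7 rose and 0 fell under either scaling. Camera called the list higher (adjusted p = 1.66e-06, and adjusted p = 0.103 with an estimated correlation). CREB targets were called higher with 6 of 13 risen (adjusted p = 1.57e-05, and adjusted p = 0.409 with an estimated correlation). Immediate early genes were too, with 4 of 18 risen, or 5 under either scaling (adjusted p = 0.00025, and adjusted p = 0.615 with an estimated correlation). The immediate early genes that rose numbered 1 without insulin replicate 1 and 2 without PBS replicate 1, 2 or 3.

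Genes of gluconeogenesis went both ways at point 4. Of 13, 4 rose (G6pc, Tat, Ppargc1a by 1.44 ± 0.14 and Got1 by 0.98) and 3 fell (Pcx by 0.56, Fbp1 by 0.53 and Slc37a4 by 0.57), and under either scaling 4 rose and 2 fell. None of the 3 that fell was left when insulin replicate 1, insulin replicate 2 or PBS replicate 3 was out. The lowest named genes included the sphingosine-1-phosphate transporter Spns2 at -1.93, the chemokine Cxcl10 at -1.88, the progestin receptor gene Paqr7 at -1.85, and the immunoproteasome subunit Psmb9 at -1.79. Of 19 fatty acid synthesis genes 4 fell and 0 rose as deposited (6 and 1 over the list alone), and 3 fell and 1 rose under either scaling. The number that fell was 0, 1, 2 and 1 without insulin replicate 1, insulin replicate 2, PBS replicate 2 and PBS replicate 3. Of 23 fatty acid oxidation genes 6 fell and 0 rose as deposited, 4 fell and 1 rose under either scaling, and 2 fell without insulin replicate 2 or PBS replicate 3. Of 12 autophagy and lysosome genes 1 fell and 0 rose as deposited, and 1 fell and 2 rose under either scaling. Camera called none of the gluconeogenesis, fatty acid synthesis, fatty acid oxidation and autophagy lists at point 4, where 1416 of all 13589 genes fell. With only the 6 libraries of point 4 in the fit 101 genes were called, and the calls of Spns2, Cxcl10, Paqr7 and Psmb9 ended there (adjusted p = 0.0873, 0.0544, 0.0628 and 0.053). The count of genes called was 716 and 635 without insulin replicates 1 and 2, 1062 and 734 without PBS replicates 1 and 3, and 659 without the insulin replicate 1 series.

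At point 5, Pdk4, Igfbp1, Lpin1 and Txnip were higher in insulin than in PBS. Pdk4 differed by 3.05 ± 0.26, Lpin1 by 2.17 ± 0.28, Trp53inp1 by 2.06 ± 0.19 and the histone methyltransferase Setdb2 by 1.97 ± 0.23 (SE, n = 3 per group, adjusted p = 1.51e-07, 3.44e-05, 3.45e-07 and 8.19e-06). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, stood at 8.43 ± 0.808 FPKM against 0.148 ± 0.172 (SD, adjusted p = 0.0236), a call that ended under 6 of 17 alternatives, among them without insulin replicate 1 or 3 (adjusted p = 0.07 and 0.0602) or PBS replicate 2 or 3 (adjusted p = 0.057 and 0.0708). Of 18 insulin receptor and Foxo targets 5 rose and 2 fell as deposited, and 6 rose and 0 fell under either scaling. Camera called the list higher (adjusted p = 0.00098, and adjusted p = 0.409 with an estimated correlation). Glucocorticoid receptor targets were called higher with 5 of 15 risen and 1 fallen, counts that were 7 and 0 with median-ratio scaling and 6 and 0 with quantile normalization (adjusted p = 5.28e-07, and adjusted p = 0.0902 with an estimated correlation). CREB targets were called higher with 4 of 13 risen (Crem, Ppargc1a, G6pc and Tat) and 1 fallen, Per1, or 5 and 0 under either scaling (adjusted p = 0.000183, and adjusted p = 0.54 with an estimated correlation). Ppargc1a, G6pc and Tat are also in the gluconeogenesis list, and Tat and Per1 in the glucocorticoid receptor list. Immediate early genes were called higher with only Klf10 risen, by 1.17 ± 0.24 (adjusted p = 0.00963, and adjusted p = 0.975 with an estimated correlation), a call that ended with median-ratio scaling (adjusted p = 0.144).

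The fatty acid and sterol synthesis lists were not called by camera at point 5 (adjusted p = 0.746 and 0.921), though single members fell. Of 19 fatty acid synthesis genes 6 fell (Srebf1, Fasn by 1.15, Acss2 by 0.73, Acaca by 0.62, Agpat2 and Pgd) and 1, Lpin1, rose, with 9 and 2 over the list alone. The counts were 3 and 2 with median-ratio scaling and 4 and 2 with quantile normalization, and 3 fell without insulin replicate 1. Of 25 sterol synthesis genes 4 fell, including Srebf2 by 0.73 and Acat2 by 0.70, and Pmvk rose by 2.35 ± 0.46. With median-ratio scaling 4 fell and 2 rose. Of 23 fatty acid oxidation genes 3 fell and 1 rose as deposited, whereas 2 fell and 4 rose with median-ratio scaling and 2 fell and 3 rose with quantile normalization. Of 12 autophagy and lysosome genes 0 passed as deposited, and 4 rose and 0 fell under either scaling. Of 17 clock genes 6 fell and 0 rose as deposited, including Per3 by 0.91, whereas 3 fell and 2 rose under either scaling. The number that fell was 3 without insulin replicate 1 and 2 without PBS replicate 2. Camera called none of the fatty acid oxidation, autophagy and clock lists at point 5, where 2194 of all 13589 genes fell. The lowest named genes also held Paqr7 at -1.96, the potassium channel gene Kcnk5 at -1.77, Notum, a secreted inhibitor of Wnt signalling, at -1.65 and the tight junction gene Cldn3 at -1.64. At point 5, 1115 genes were called with only its 6 libraries in the fit, 1121 without insulin replicate 1, 1345 without PBS replicate 3 and 1107 without the insulin replicate 1 series.

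The difference between insulin and PBS itself depended on the sampling point for 241 genes by limma's F test of the interaction, and for 250 with lane as a fixed block. Where equal lane numbers stand for the same lane and run, a constant offset between lanes cancels in the interaction for points 1 to 4. The offset does not cancel for point 5, where insulin replicate 1 lay on another lane than at the other points. Txnip, lower in insulin at point 2 and higher at points 4 and 5, had an adjusted p of 3.12e-10. Its difference less that at point 1 was -1.76 at point 2 and 1.95 at point 5. For Pdk4 these values ran from -0.70 at point 2 to 3.34 at point 4 (adjusted p = 7.59e-08). For Rgs16 they ran from -3.64 at point 2 to 2.42 at point 5 (adjusted p = 1.81e-05). For Lpin1 they were 1.83 at point 2 and 4.00 at point 5 (adjusted p = 1.81e-05). Nr4a1 and Sik1 had values of 4.77 and 3.52 at point 2 (adjusted p = 1.82e-05 and 0.00051). Of the textbook targets, Igfbp1 (adjusted p = 0.0375), Irs2 (adjusted p = 0.0486) and Srebf1 (adjusted p = 0.0348) passed. The interaction of Irs2 and Srebf1 was not examined under the alternatives, so how firmly these calls hold is not known. The interaction called 145 genes without the filter on low values, and 118, 122 and 98 without insulin series 1, 2 and 3. It called 70, 112 and 95 without PBS series 1, 2 and 3, a series being the 5 libraries of a replicate number. The call of Igfbp1 ended under 11 of 17 alternatives, among them without insulin series 1, 2 and 3 (adjusted p = 0.069, 0.0784 and 0.165) and PBS series 1, 2 and 3 (adjusted p = 0.346, 0.0628 and 0.117).

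**Figure D3:**
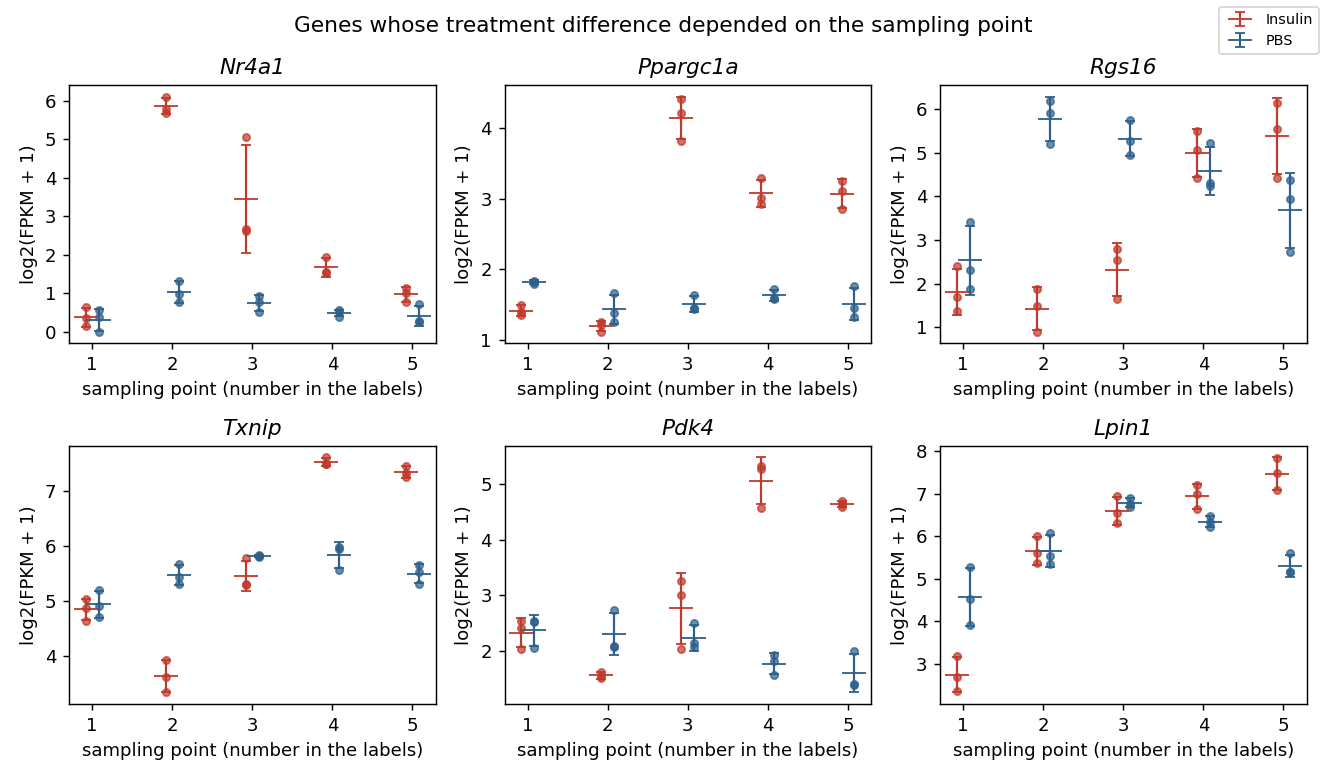
Log2(FPKM + 1) of Nr4a1, Ppargc1a, Rgs16, Txnip, Pdk4 and Lpin1 at each numbered sampling point, for insulin (red) and PBS (blue), with a point per library, a dash at the mean of the 3 libraries and bars of 1 SD. Nr4a1 stands at 57.7 FPKM in insulin and 1.06 FPKM in PBS at point 2, and Pdk4 at 33.3 and 2.42 FPKM at point 4; each panel has its own vertical range, which does not start at 0.

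The vehicle control was not constant. Within PBS, 444 genes differed among the 5 points by limma's F test, and the genes with the widest range held several clock genes. Dbp was above its point 1 level by 0.98, 2.76, 3.23 and 2.93 at points 2 to 5 (adjusted p = 0.000225). Ciart was above it by up to 3.00 (adjusted p = 9.45e-06) and the clock-controlled protease gene Usp2 by up to 2.70 (adjusted p = 1.16e-06). Rgs16 was above point 1 by 3.24 at point 2 and 1.14 at point 5 (adjusted p = 0.000619), Chd9 by up to 2.82 (adjusted p = 4.11e-06) and Egr1 by 2.72 at point 2 (adjusted p = 0.00661). Elovl3, a fatty acid elongase, was below it by up to -2.52 (adjusted p = 0.0131). Within PBS, 128, 146 and 199 genes were called without PBS series 1, 2 and 3. The calls of Egr1 and Elovl3 ended without PBS series 1 (adjusted p = 0.0888 and 0.14), PBS series 2 (adjusted p = 0.0752 and 0.0609) or PBS series 3 (adjusted p = 0.134 and 0.0628).

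Within insulin, 1804 genes differed among the points. Nr4a1 was above its point 1 level by 5.48 at point 2 and 0.59 at point 5 (adjusted p = 1.12e-09). Lpin1 was above it by 2.91, 3.86, 4.20 and 4.73 at points 2 to 5 (adjusted p = 7.5e-11). For Mt2 the values were 1.49, 2.54, 3.43 and 3.79 (adjusted p = 1.75e-06), and for Mt1 1.22, 2.08, 3.09 and 3.67 (adjusted p = 1.47e-06). Txnip was below point 1 at point 2 by -1.22 and above it by 2.69 at point 4 (adjusted p = 1.86e-14). Rgs16 differed from point 1 by -0.39, 0.51, 3.18 and 3.56 at points 2 to 5 (adjusted p = 8.17e-07). In PBS it was above point 1 by 3.24 and 2.78 at points 2 and 3. Its fall against PBS at those points thus went with a higher level in PBS, with little change in insulin. The phosphatase gene Ptp4a1 was above point 1 by up to 4.35 (adjusted p = 0.00945). The number of genes called was 1021, 876 and 923 without insulin series 1, 2 and 3, and 975 among genes at a mean FPKM of 5 or more. The call of Ptp4a1 ended without insulin series 2 (adjusted p = 0.112).

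Markers of other liver cells were measured beside these groups. Of 10 Kupffer cell markers, genes of the resident macrophage, 6 fell at point 4 and 0 rose (7 and 0 over the list alone), including C1qb by 1.03, Cd5l by 0.92, and Csf1r by 0.79. The call of Cd5l ended without PBS replicate 1 (adjusted p = 0.0617). Camera called the list lower (adjusted p = 0.00101, and adjusted p = 0.975 with an estimated correlation). The number that fell was 4 with median-ratio scaling and 5 with quantile normalization, and 3 and 2 without insulin replicate 1 and PBS replicate 1. The list call ended without PBS series 1 (adjusted p = 0.0927). Of 9 sinusoidal endothelial markers 5 fell at point 5 and 0 rose, which was 2 with median-ratio scaling, 1 with quantile normalization, 1 without insulin replicate 1 and 3 without PBS replicate 2 or 3, and camera did not call that list (adjusted p = 0.0556). Of the 8 stellate cell markers, 2 fell at point 5, including Ecm1, whose call ended without insulin replicate 1 (adjusted p = 0.0903) or PBS replicate 3 (adjusted p = 0.0628). With median-ratio scaling 1 also rose. Camera did not call the stellate cell list there (adjusted p = 0.377). Red blood cell genes were called higher by camera at point 2 (adjusted p = 0.0334, and adjusted p = 0.975 with an estimated correlation) with 0 of 5 passing, a call that ended without insulin series 3 (adjusted p = 0.0581) or PBS series 2 (adjusted p = 0.122), or with median-ratio scaling (adjusted p = 0.0814). Of 3 measured cholangiocyte markers, Sox9 fell at point 4, a call that ended with quantile normalization and without insulin replicate 2 (adjusted p = 0.127) or PBS replicate 2 or 3 (adjusted p = 0.0623 and 0.0663). The neutrophil, pancreatic acinar and adipocyte lists had 2, 1 and 1 measured genes and were not tested as lists, and the lymphocyte and mesothelium lists had 0. Among the insulin libraries, the 5 of replicate 1 stood apart in CT010467.1, an annotated ribosomal RNA gene on chromosome 17 (39846353 to 39848827). They held it at 64759 to 69874 FPKM, against 3279 to 7880 FPKM in the other 25 libraries.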

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

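The counts of other splits and the tests of an offset of whole libraries, of the ribosomal RNA series, of abundant genes without a series, of a lane offset, of CREB targets outside the immediate early list and of clock genes at point 1 were chosen after the results they bear on were seen. The insulin minus PBS difference depended on the sampling point for 241 genes. Of 100 groupings that exchanged treatments within each point, 8 gave as many genes, and the highest other gave 2736, which points to the treatment difference shared by the points entering such groupings. After each treatment's mean was removed from every gene, 1 of 100 groupings, the real one, gave 241 genes, and the highest other gave 12. Libraries of the insulin replicate 1 series resembled each other, with a median correlation of deviations from group means of 0.216, against -0.111 with the other insulin series. In the other 5 series the medians ran from -0.0192 to 0.087. With points exchanged only within each series, after each point's mean was removed, 1 of 100 groupings, the real one, gave as many genes. The highest other gave 1, so chance is argued against there, at the smallest share that 100 groupings can give. With whole series exchanged, the 10 splits are too few for a share under 0.05, with 241 genes for the real split and 0 for the highest other. The named genes whose differences depended on the point by limma's interaction test included Txnip (adjusted p = 3.12e-10), Pdk4 (7.59e-08), Rgs16 (1.81e-05), Lpin1 (1.81e-05), Nr4a1 (1.82e-05), Sik1 (0.00051), Srebf1 (0.0348), Igfbp1 (0.0375) and Irs2 (0.0486). Srebf1 and Irs2 were not examined under the alternatives for the interaction, and the call of Igfbp1 ended under several of them.

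For the single-point comparisons, the 10 splits of the 6 libraries are too few for a share under 0.05. The real splits called 1, 184, 1284, 1799 and 2596 genes at points 1 to 5, and the highest other splits called 7, 1, 1, 0 and 3, so that 3 of 10 splits gave as many at point 1 and 1 of 10, the real split, at each other point. For the differences among points within PBS and within insulin, 1 of 100 groupings, the real one, gave as many as 444 and 1804 genes. The highest others gave 29 and 324. With points exchanged only within each series, 1 of 100, the real one, gave as many and the highest others gave 3 and 749. Chance is therefore argued against for both, at the smallest share that 100 groupings can give.

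The lower calls outnumbered the higher calls in insulin at points 3 to 5. The ribosomal RNA of the insulin replicate 1 series is argued against as the whole cause at points 3 and 5. Without that series the median difference of all genes went from -0.143 to -0.120 and from -0.172 to -0.126. With 1 more library of the point out it stayed at -0.106 and -0.0874 or below, past the bounds of -0.0717 and -0.0858 set at 0.5 of the shift, though narrowly at point 5. It stays open at point 4, where the median went from -0.142 to -0.0900 and reached -0.0454 with 1 more library out. Without the series 269, 259 and 271 genes were higher and 424, 400 and 836 lower at points 3, 4 and 5, so that 38.8%, 39.3% and 24.5% of the calls were higher. A few abundant genes stay open as the source of part of the shift. The share of length-weighted FPKM outside the 20 most abundant genes was 76.3% in insulin and 79.6% in PBS at points 3 to 5, a log2 ratio of -0.0604. It lay between -0.0673 and -0.0472 without any 1 of the 18 libraries, above the -0.07 set for it. It was -0.0168 without insulin series 1, the ribosomal RNA series. Most of it therefore came with that series, so this explanation overlaps with that of ribosomal RNA. The ratio was past that bound at -0.0786 and -0.0868 without insulin series 2 and 3, where series 1 weighs more. An offset of whole libraries stays open. Median-ratio scaling gave 52.4% higher calls at point 5, but it centres the differences and so fixes this outcome. Whether an offset came from lanes, which no library of the other treatment shares, or from a wide fall of transcripts in the liver was not tested and stays open.

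CREB targets were higher in insulin at point 2. A constant lane offset alone is argued against, if equal lane numbers stand for the same run. The difference at point 2 less that at point 1 had a median of 1.21 and a lower quartile of 0.48 over all 13 members. The median stayed between 1.04 and 1.43 without any 1 of the 12 libraries, and the lane numbers are the same at both points. An offset masked at point 1 by an opposite response was not tested. Dependence on a single library stays open for the number of calls, which fell to 3 without insulin replicate 2, while the list median stayed between 0.95 and 1.38 without any 1 of the 6 libraries. A hypothesis is higher cAMP and CREB signalling in insulin-treated mice, such as a hormonal response to falling glucose might give. Outside the immediate early list 7 of 12 members rose, a number that the 8 risen members and the 1 shared gene nearly fix, so it decides nothing. Plasma glucose and glucagon and phosphorylated CREB, measured in the same mice, would test the hypothesis, and none was measured in the data used here.

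Glucocorticoid receptor targets were lower in insulin at point 1. A constant lane offset is argued against as the whole source of the course over the points. The median member rose by at least 1.03 between its difference at point 1 and those at points 4 and 5. Point 4 has the lane numbers of point 1. An offset together with a rise at points 4 and 5 would give the same values, so an offset stays open at point 1 itself. A single library is argued against, because the list median stayed at -0.54 or below without any 1 of the 6 libraries. A different time of day in the treatments stays open, with 1 clock gene past the test over the list alone and a 95% interval of the Dbp difference of -1.54 to 0.40, too wide to decide. A difference in glucocorticoid tone between the treatments may be the source and was not tested.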

How the results depend on the processing

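None of the named genes reversed its direction past the test under any alternative run, and of the 29, 60, 61 and 62 named genes called at points 2 to 5, 19, 26, 14 and 30 stayed called under every alternative run. Where a single replicate was left out, the counts of genes called ranged from 0 to 62 at point 1, 84 to 456 at point 2, 583 to 845 at point 3, 635 to 2396 at point 4 and 1121 to 2545 at point 5. With a series of 5 libraries left out they ranged from 70 to 122 for the interaction, 128 to 395 within PBS and 876 to 1629 within insulin, where fewer samples lower the counts. Without the filter, which adds low genes to the correction, 3 genes were called at point 1, 810 at point 3 and 145 for the interaction. The pseudocount of 0.1 gave 3 at point 1, median-ratio scaling 2 and quantile normalization 4. With only the 6 libraries of a point, 0, 62, 1018, 101 and 1115 genes were called at points 1 to 5. All points lose the same degrees of freedom in such a fit. That loss alone does not account for 101 of 1799 left at point 4 beside 1018 of 1284 at point 3. The calls at point 4 therefore lean on the spread shared with the other points. The filter at a mean of 5 FPKM, with fewer genes, left 975 within insulin. Of the alternatives chosen after seeing the data, leaving out the insulin replicate 1 series gave 2, 693, 659 and 1107 at points 1, 3, 4 and 5, and centring on the median of genes at 5 FPKM or more gave 3 at point 1. The genes with a value in every library gave counts within 1.5 times the main ones. So did leaving out PBS replicate 3 of point 3 for the other points and the F tests, but point 3 itself fell to 583. The series left out of the gene list tests were also chosen after seeing the data. Of the gene lists, 4 were called with an estimated correlation and 14 with fry. Replicate numbers did not pair the treatments: over 15 pairs of same-numbered insulin and PBS libraries the correlation of deviations ran from -0.11 to 0.12, 1 pair lay over 0.1, and 5 had their own number as the best match. With the replicate block, 5, 450 and 1957 genes were called at points 1, 2 and 3, and the other counts stayed within 1.5 times. Except where the construction is given, the cause was not tested. Depth was only estimated, so no limit per gene is given.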

Other observations

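Several fixed lists changed in few members. Over all 13589 genes tested, 986, 1416 and 2194 fell and 298, 383 and 402 rose at points 3, 4 and 5. A few fallen members in a list can therefore reflect the genes as a whole. Of the lists in this paragraph, camera called only the acute phase list, at point 2. Of 19 glycolysis and glycogen genes, 2 fell at point 3, 1 rose and 2 fell at point 4, and 1 rose and 5 fell at point 5, where Pygl and Pgm1 each fell by 0.51. Under either scaling 1 fell at point 3, and 2 rose and 0 fell at point 4. At point 5, 2 rose and 2 fell with median-ratio scaling and 1 rose and 3 fell with quantile normalization. As deposited, 1, 2 and 2 fell at point 5 without insulin replicate 1, PBS replicate 2 and PBS replicate 3. Of 16 ATF4 targets, Trib3, a pseudokinase, fell by 1.14 and Atf4 rose by 0.74 at point 2, the latter a call that ended without insulin replicate 1 or 2 (adjusted p = 0.0729 and 0.0625) or PBS replicate 3 (adjusted p = 0.116), 1 rose and 3 fell at point 3, and 1 rose and 2 fell at point 4. Under either scaling 1 rose and 2 fell at point 3, and 2 rose and 2 fell at point 4. Of 19 acute phase genes, Socs3, a feedback inhibitor of cytokine signalling, rose at point 2 by 2.13 ± 0.33, and camera called the list higher there (adjusted p = 0.0073, and adjusted p = 0.975 with an estimated correlation), a call that ended without insulin series 2 (adjusted p = 0.519). At points 3, 4 and 5, 3, 1 and 2 acute phase members fell, and 1 fell at point 3 without insulin replicate 1 or PBS replicate 2. With median-ratio scaling 0 and 1 fell at points 4 and 5, and with quantile normalization 1 and 0. Of 17 ER chaperone and unfolded protein response genes, 1 rose and 1 fell at point 3 and 2 fell at point 4. Under either scaling 1 rose and 0 fell at point 3, and 2 rose and 2 fell at point 4. Among these the call of Xbp1 at point 4 ended without insulin replicate 1 (adjusted p = 0.0656). Of 11 heat shock genes, Hspb1 fell by 1.13 at point 4, and under either scaling 1 rose at each of points 3 and 5. Of 12 bile acid genes, 1 fell at each of points 3, 4 and 5, the last of them the bile acid transporter gene Slc10a1, by 0.55. Under either scaling 0 fell at points 3 and 4 and 1 fell at point 5, and with median-ratio scaling 1 rose at point 4. Of 10 periportal genes 1 and 3 fell at points 4 and 5 (1 at point 5 without insulin replicate 1), and of 10 pericentral genes 1, 2 and 2 fell at points 3, 4 and 5. Under either scaling 0 periportal genes fell at point 4. At point 5, 1 rose and 1 fell with median-ratio scaling and 2 fell with quantile normalization. Pericentral genes that fell numbered 0, 1 and 0 at points 3, 4 and 5 with median-ratio scaling and 0 at each with quantile normalization. Of 5 replication-dependent histone genes, Hist2h2aa1 rose at point 4, a call that ended without insulin replicate 1 or 2 (adjusted p = 0.178 and 0.08) or PBS replicate 1 or 3 (adjusted p = 0.0544 and 0.0668).

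Points 4 and 5 had 172 genes called higher at both and 832 called lower at both, and points 2 and 5 had 17 and 26. If the calls of the points were independent, 11.3 and 229 would be expected for points 4 and 5, and 2.48 and 16.1 for points 2 and 5. The points share series, lanes and a fitted spread per gene, so independence is not given. No value that allows for this sharing was computed.

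The comparison of single libraries with the rest was chosen after seeing the data. The library of PBS replicate 3 at point 3 held values for intestinal genes. Defa24 stood at 43.1 FPKM, Reg3b at 34.6 FPKM and Reg3g at 25.2 FPKM in it, and each had no value in the other 29 libraries. In all, 22 genes at 5 FPKM or more in that library were under 0.5 FPKM in the other 29, against at most 1 such gene in any other library. These genes were below the filter and entered only the fit without it. With that library left out, camera also called the sterol synthesis list at points 2 and 3 (adjusted p = 0.035 and 0.000246, against 0.0562 and 0.617 with it). It also called the sinusoidal endothelial list at points 3 and 5 (adjusted p = 0.00278 and 0.0337, against 0.0917 and 0.0556). The library of PBS replicate 2 at point 5 held 5.03% of its FPKM in Mup genes, the major urinary proteins. The other PBS libraries held 14.8% to 26.2% and the insulin libraries 13.5% to 27.7%. Without that library the median difference of all genes at point 5 was -0.137, against -0.172 with it. It ran from -0.208 to -0.126 over the 6 libraries of the point left out in turn.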
